A study of Homo sapiens with 18 samples.

How the data were processed

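The data are RNA-seq counts from 18 libraries of cultured K562 cells in 6 groups of 3. Per the labels' protocols, cells were transduced with lentivirus in the presence of 4 µg/ml polybrene and selected with 1 µg/ml puromycin from about 96 hours after transduction, polyadenylated RNA was purified on oligo-dT beads, and double-stranded cDNA was fragmented and tagged with a Nextera transposase, a preparation that does not mark the strand. Reads from a gene and its antisense partner therefore cannot be told apart. The authors deposited 1 file of raw counts per library without a header, with a RefSeq transcript accession and a count on each of 40709 lines. The submitters' processing notes name Bowtie2, SAMtools, Picard, R 3.1.2, DESeq and the genome build hg19, without saying what each did; the counting tool, the annotation release and the handling of reads with several alignments are not stated.

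Every deposited count was even (0 odd values in all files). In 1865 genes with a pair of transcripts the split of counts between the pair varied between libraries with a median chi-square per degree of freedom of 2.11 on the counts and 1.055 on the halved counts, so each fragment was taken to have been counted as its 2 mates. The tests ran on the deposited counts, and halved counts were an alternative. Library totals ranged from 22805964 to 34032962 counts. Transcripts were summed to genes. Of the accessions 39324 matched the RefSeq gene table of the GRCh38 assembly and 517 a GENCODE table, together 97.87% of accessions and 99.02% of counts, and 868 were kept under their own accession, which left 24395 genes. The tables of the reference served for names, chromosomes and neighbours only, since the files use another build. No mitochondrial transcript was among the rows, so that measure of RNA quality was not available.

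The groups were compared in 10 contrasts fixed before the data were examined, each with all 18 libraries in 1 fit of 6 group means: KRAB_CR4 and KRAB_CR10 against KRAB_no_gRNA and against the dCas9 group of the same gRNA, the mean of the KRAB against dCas9 differences, both dCas9 groups against KRAB_no_gRNA, KRAB_no_gRNA against no_lentivirus, KRAB_CR4 against KRAB_CR10, and the difference of the KRAB effects. Counts were filtered with filterByExpr, which kept 14713 genes holding 99.97% of the counts, scaled by TMM, and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 21.6%. Standard errors of log2 fold changes were derived from the test statistic, and 95% intervals used the residual degrees of freedom of the libraries alone. CPM values are TMM-scaled and untransformed. Intervals and depths cover counting and library spread, not molecules, since the reads carry no molecular identifiers.

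Lists of genes were also fixed before the data were examined: the beta-globin and alpha-globin clusters, neighbours on chromosome 11, haem synthesis and iron uptake, erythroid membrane and maturation, erythroid transcription factors, megakaryocyte markers, myeloid and lymphoid markers, interferon response, p53 targets, the unfolded protein and amino acid response, sterol synthesis, immediate early genes, cell cycle, hypoxia and glycolysis, KRAB co-repressors, ZNF10, which shares sequence with the construct, and replication-dependent histones as a measure of RNA without poly(A). They were tested with camera (limma 3.58.1) on voom values with the preset correlation, adjusted over the 17 tested lists of a comparison, and again with an estimated correlation. Named genes followed a rule fixed at the same time: the globin genes and ZNF10 in every comparison; the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 1 CPM and did not overlap between groups (no such condition for the mean over both gRNAs and for the difference of effects); up to 4 passing members per list; and where fewer than 3 genes outside the globin clusters passed, the 5 with the smallest p. Exceptions are marked in the text.

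Whether library numbers pair the libraries was checked by correlating deviations from the group means over 11753 genes. All 30 pairs of lentiviral libraries with the same number correlated above 0.1, from 0.17 to 0.88, and pairs with different numbers ranged from -0.77 to 0.60. Of these 60 different-numbered pairs 17 were also above 0.1, each a number 1 with a number 2. Same-numbered pairs ranged from 0.34 to 0.75 for number 1, 0.17 to 0.60 for number 2 and 0.74 to 0.88 for number 3. With number 3 far off in every group, deviations of 1 and 2 from the mean tend to correlate however they are matched. Of the 15 same-numbered pairs with an untransduced library 5 were above 0.1. The check thus shows that libraries numbered 3 stand apart together, and cannot by itself tell whether numbers 1 and 2 pair the libraries. The numbers were read as pairing the lentiviral libraries only. A fit with the replicate number as a block on these 15 libraries, with 14599 genes and a biological coefficient of variation of 10.5%, was added after the data were examined.

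Before use, the scripts were tested on simulated data with known answers: negative binomial counts with the real library sizes, dispersions and gene means, equal in all groups except for 200 genes changed in KRAB_CR4, which was compared with KRAB_no_gRNA over a mean of 14508.75 genes per run for edgeR on all 18 libraries, 14419.25 for the block fit and 14508 for DESeq2. Over 4 runs edgeR recovered 11.3%, 52.8% and 82% of changes of 1.5-fold, 2-fold and 4-fold with 2.75 false calls per run, and the block fit 59.4%, 80.5% and 95.1% with 10 false calls per run. DESeq2 recovered 22.4%, 68.7% and 89.2% in 1 run with 25 false calls. These shares hold for 200 changed genes, and recovery would be lower where few genes change. A changed list of 20 genes was called in 4 of 4 runs and an unchanged one in 0 of 4.

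Alternatives fixed before the data were examined were DESeq2 1.42.0, median-ratio size factors, no count filter, a filter at a mean of 50 counts, a fit of the compared groups alone, the replicate block on all 18 libraries, summed paralogs, an adjusted p threshold of 0.01, leaving out each library, camera with an estimated correlation or the block, and for the shared calls other control groups and leaving out the globin genes. Added after the data were examined were fits of the lentiviral libraries alone with and without the block, halved counts, leaving out lentiviral libraries numbered 3, and leaving out ribosomal RNA. Other splits of the same libraries into groups were refitted for comparison. Overlap and correlation of the 2 gRNAs were set beside 20 simulations of unchanged groups against the same controls, and 20 more, added after the data were examined, kept the replicate effects of the lentiviral libraries and were fitted with the block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the main results.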

Results

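RNA was sequenced from K562 cells, a human erythroleukaemia line that expresses embryonic and fetal globin genes, after lentiviral delivery of a catalytically inactive Cas9 (dCas9), alone or fused to the KRAB repressor domain, with or without a guide RNA (gRNA) aimed at HS2, a distal enhancer of the beta-globin gene cluster. Each of the 6 groups held 3 libraries. The group KRAB_no_gRNA carried the repressor without a gRNA, dCas9_CR4 and dCas9_CR10 carried dCas9 without a repressor domain and 1 of the gRNAs named CR4 and CR10, KRAB_CR4 and KRAB_CR10 carried the repressor with a gRNA, and no_lentivirus was not transduced. The 18 libraries held between 22805964 and 34032962 counts, at 2 counts per sequenced fragment, and 14713 genes were tested. Ribosomal RNA took 4.02% of the counts in KRAB_CR4 library 2 and 3.52% in KRAB_CR10 library 1, against at most 1.5% in every other library.

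The libraries numbered 3 in the 5 lentiviral groups stood apart from those numbered 1 and 2, and the 3 untransduced libraries stood apart from each other. The first principal component held 61.0% of the variance of the 2000 genes used. On it the lentiviral libraries numbered 3 lay between -21.9 and -7.2, those numbered 1 and 2 between 8.6 and 18.5, and no_lentivirus library 2 at -44.9. Same-numbered lentiviral libraries deviated together from their group means, though libraries numbered 1 and 2 often did so across numbers too. Where a fit with the replicate number as a block, on the 15 lentiviral libraries alone, changed a call, its values are given below.

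**Figure D1:**
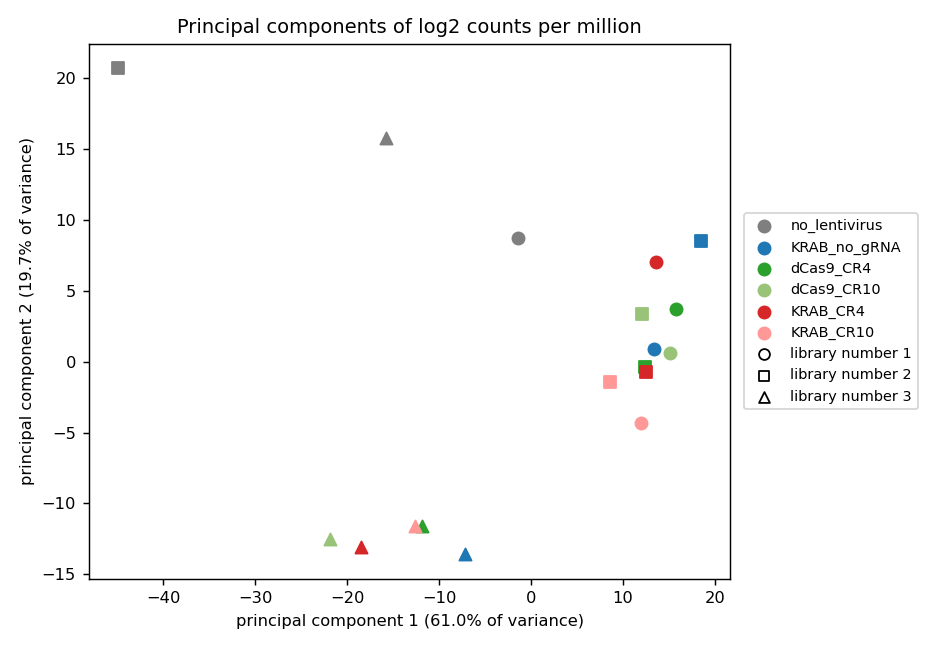
Principal components 1 and 2 of log2 CPM over 2000 genes, 1 point per library, with colour for the group and shape for the library number; the axes give each component's share of the variance in percent. The 5 lentiviral libraries numbered 3 lie together at the lower left, and no_lentivirus library 2 lies at -44.9 on component 1.

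The comparison of KRAB_CR4 with KRAB_no_gRNA asks what dCas9-KRAB does when CR4 brings it to HS2. The embryonic and fetal genes of the beta-globin cluster on chromosome 11 fell. HBE1 (NM_005330), which encodes embryonic epsilon-globin, fell 7.43-fold, from 457 ± 17.8 to 61.6 ± 6.2 counts-per-million (CPM; SD, n = 3 and 3). The fetal gamma-globin genes HBG2 (NM_000184) and HBG1 (NM_000559) fell 3.84-fold and 3.26-fold, HBG2 from 921 ± 31.4 to 240 ± 22.5 CPM and HBG1 from 837 ± 30.2 to 257 ± 21.3 CPM. In each of the 3 genes every KRAB_CR4 library lay below every KRAB_no_gRNA library. The log2 fold changes were -2.89 ± 0.14 (SE) for HBE1, -1.94 ± 0.16 for HBG2 and -1.70 ± 0.16 for HBG1, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 2.36e-09, 5.91e-06 and 3.11e-05.

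HBG1 and HBG2 are near-identical copies, and the counting could have split reads between them in an unknown way; their summed counts fell by 1.82 on the log2 scale. The other members of the cluster were at low levels. The pseudogene HBBP1 read 4.3 ± 1.26 against 23.2 ± 0.572 CPM and the delta-globin gene HBD 4.2 ± 1.57 against 13.7 ± 3.75 CPM (SD, n = 3 and 3). Neither passed in the fit of all 18 libraries (edgeR adjusted p = 0.241 and 0.999). HBBP1 passed with the lentiviral libraries alone, without the block (edgeR adjusted p = 9.48e-05) and with it (2.14e-09), with only the 2 groups fitted (0.00643) and with DESeq2. HBD passed only with the lentiviral libraries and the block (edgeR adjusted p = 7.92e-06). Adjusted over the list alone, 5 of the 6 tested cluster genes were lower. The sixth, the adult beta-globin gene HBB, had at most 10 counts in any library of the 2 groups. As a list the cluster fell (camera adjusted p = 9.98e-39, and adjusted p = 0.000847 with an estimated correlation).

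No gene outside the cluster passed in this comparison in the edgeR fit of all 18 libraries. Among the 4 tested genes of the alpha-globin cluster on chromosome 16 none passed over all genes. HBA1 read 472 ± 51.8 against 398 ± 58 CPM, with a log2 fold change of 0.25 and a 95% interval from -0.18 to 0.68, and HBZ read 305 ± 58.1 against 236 ± 70.3 CPM, with an interval from -0.30 to 1.03. None of the 27 tested genes near the beta-globin cluster on chromosome 11 passed. The 5 smallest p outside the globin clusters belonged to SERPINB8, CA1, TNS1, GDPGP1 and TPTEP2, none of which passed in that fit. SERPINB8 had 0 counts in each KRAB_CR4 library and 6 to 20 counts in the KRAB_no_gRNA libraries, and CA1, an erythroid carbonic anhydrase, read 13.3 ± 1.92 against 7.6 ± 1.87 CPM (SD, n = 3 and 3). In all, edgeR called 3 genes, 251 genes had an unadjusted p under 0.05, and DESeq2 called 6, adding HBBP1, CA1 and SERPINB8.

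With the replicate block on the lentiviral libraries the count was 6, against 4 on these libraries without it and 3 with it on all 18. The 1 call outside the cluster was ACSM3, which encodes a mitochondrial medium-chain acyl-CoA synthetase. It read 159 ± 103 against 80.1 ± 41.5 CPM (SD, n = 3 and 3), with a blocked log2 fold change of 0.93 ± 0.12 (SE) and an edgeR adjusted p of 0.00044. In the fit of all 18 libraries it was 0.99 (edgeR adjusted p = 0.999), 0.32 without KRAB_CR4 library 3 and 1.5 without KRAB_no_gRNA library 3; ACSM3 was chosen after its values were seen, here and below, and among lentiviral libraries it was higher in those numbered 3. The list of erythroid membrane and maturation genes is described with the dCas9 groups. Sterol synthesis genes passed camera (adjusted p = 0.0345, and adjusted p = 0.824 with an estimated correlation), and with the block so did the alpha-globin cluster and the unfolded protein and amino acid response (adjusted p = 0.0193 and 0.00101, and adjusted p = 0.395 for each with an estimated correlation). In data simulated for KRAB_CR4 against KRAB_no_gRNA with 200 changed genes, edgeR recovered 82% of the 4-fold changes, 52.8% of the 2-fold changes and 11.3% of the 1.5-fold changes. With few changed genes the adjustment is stricter, so a single changed gene would be recovered less often, which was not simulated. HBBP1, at a log2 fold change of -2.43, did not pass in the fit of all 18 libraries.

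**Figure D2:**
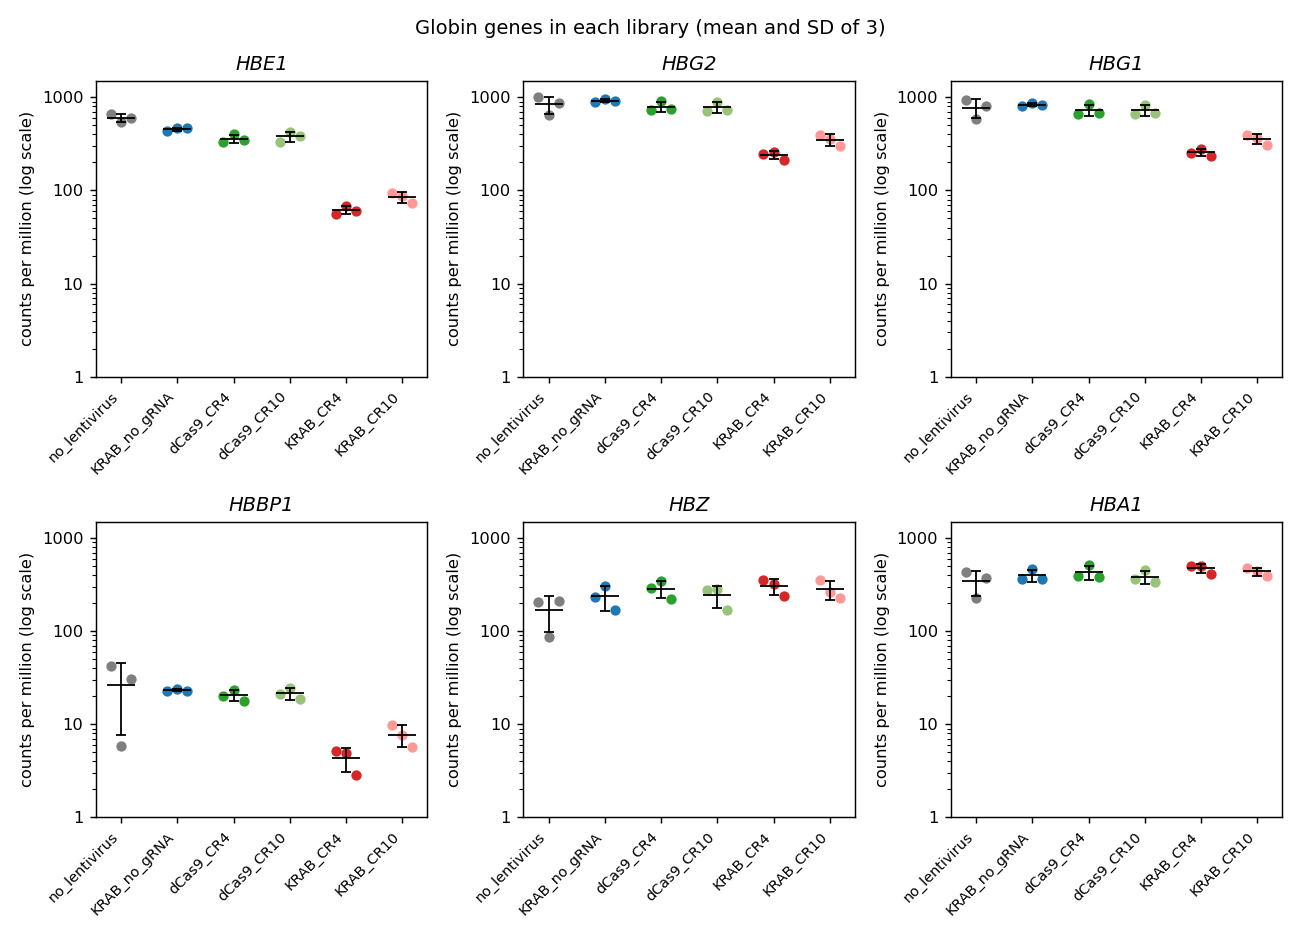
CPM on a log scale for 4 genes of the beta-globin cluster (HBE1, HBG2, HBG1 and the pseudogene HBBP1) and 2 of the alpha-globin cluster (HBZ, HBA1) in the 6 groups; points are libraries in the order 1 to 3, the long bar is the mean and the whiskers the SD of 3 libraries. In the beta-globin genes KRAB_CR4 and KRAB_CR10 lie below the other lentiviral groups, for HBE1 at 61.6 and 85 against 359 to 457.

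The same question was put for the other gRNA by comparing KRAB_CR10 with KRAB_no_gRNA. The 3 genes that passed were again HBE1, HBG2 and HBG1. HBE1 fell 5.38-fold to 85.0 ± 11 CPM, HBG2 fell 2.62-fold to 351 ± 50.4 CPM and HBG1 fell 2.34-fold to 357 ± 43.6 CPM (SD, n = 3), each with no overlap between the groups. The log2 fold changes were -2.43 ± 0.14 (SE), -1.39 ± 0.16 and -1.23 ± 0.16, with edgeR adjusted p of 3e-08, 0.000659 and 0.00279. HBBP1 read 7.75 ± 2.09 CPM and HBD 5.73 ± 2.55 CPM, and neither passed in the fit of all 18 libraries. With the lentiviral libraries alone HBBP1 passed without the block (edgeR adjusted p = 0.0134), and both passed with it (2.14e-06 and 0.000524). Over the list alone 5 of the 6 cluster genes were lower, and the cluster fell as a list (camera adjusted p = 8.56e-28, and adjusted p = 0.00384 with an estimated correlation).

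Outside the cluster no gene passed in the edgeR fit of all 18 libraries, and no alpha-globin gene and none of the 27 neighbours passed. The smallest p belonged to CA1, LCLAT1, SLX1B, GRASLND and SKIL. CA1 read 13.6 ± 0.0707 against 7.6 ± 1.87 CPM and passed with DESeq2 alone (adjusted p = 0.0174). There were 219 genes at an unadjusted p under 0.05, and DESeq2 called 4 genes. The lentiviral libraries with the block gave 7 calls, the same libraries without it 4, and the block on all 18 libraries 3. Outside the cluster the 7 held ACSM3 (blocked log2 fold change 0.70 ± 0.12, SE, edgeR adjusted p = 0.0271) and SKIL, a SMAD-binding repressor (0.60 ± 0.11, edgeR adjusted p = 0.0411). In the unblocked fit of all 18 libraries ACSM3 was at 0.70, 0.13 without KRAB_CR10 library 3 and 1.23 without KRAB_no_gRNA library 3. With lentiviral libraries numbered 1 and 2 only, HBE1 was the 1 call. Sterol synthesis genes and replication-dependent histones passed camera (adjusted p = 0.0219 for each, and adjusted p = 0.658 and 0.654 with an estimated correlation); the histones did not pass with the block (adjusted p = 0.0601).

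The same 3 genes were called with both gRNAs, where independent lists of these sizes would share 0.000612. Across all 14713 genes the log2 fold changes of the 2 comparisons correlated at r = 0.58, but unchanged groups simulated against the same KRAB_no_gRNA libraries gave a mean r of 0.50 (0.48 to 0.51 over 20 simulations) and a covariance of 0.0611, against 0.0578 observed. That simulation left out the pairing by number, which raises its covariance; with the pairing kept and the block fitted, the observed covariance was 0.0553 (r = 0.59) and the simulated one 0.0288 (0.0268 to 0.0307; mean r 0.50). Whatever else sets the KRAB_no_gRNA libraries apart also enters the observed value. Without the block, leaving out 1 library moved r between 0.36 (without KRAB_CR4 library 3) and 0.81 (without KRAB_no_gRNA library 3) and the covariance between 0.0446 and 0.245 in the same fits. Genes are not independent replicates, and with 3 control libraries the controls could not be split. With each gRNA set against its own dCas9 group, which shares no library, the 3 shared genes were found again, r was 0.14 and the covariance 0.0114, against a simulated mean r of 0.00 (-0.02 to 0.05) and covariance of 0.000697. With the pairing and the block the observed covariance was 0.0134, and the simulated one 0.000293 (-0.00186 to 0.00188). Without the globin cluster genes there could be no shared call, since every call was a globin gene, and r against the dCas9 groups was 0.13.

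**Figure D3:**
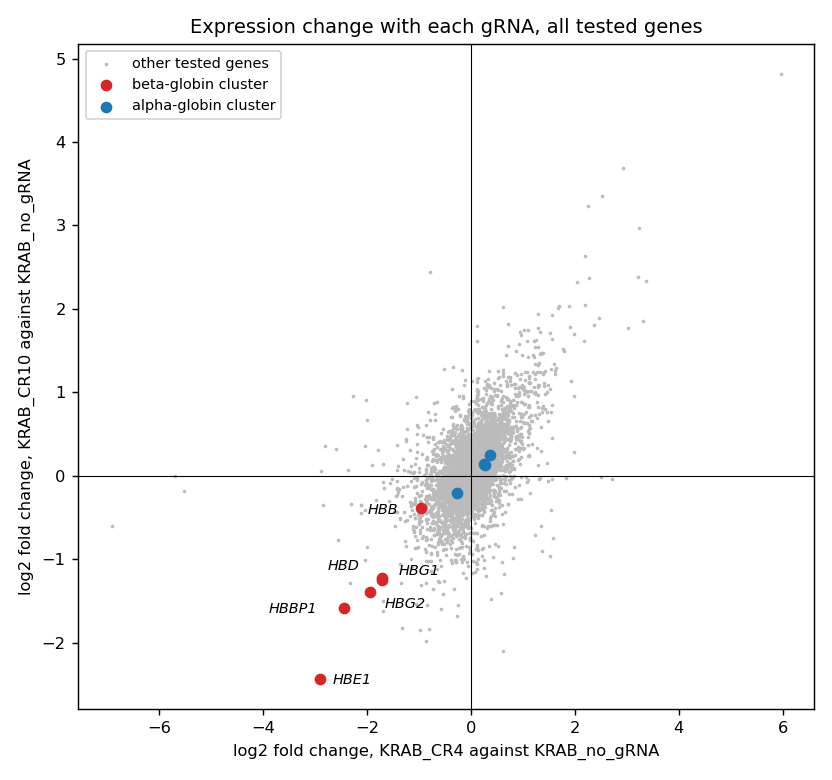
Log2 fold change of each of the 14713 tested genes in KRAB_CR4 (horizontal) and KRAB_CR10 (vertical), both against KRAB_no_gRNA, with beta-globin cluster genes in red and alpha-globin cluster genes in blue. HBE1 lies at -2.89 and -2.43, HBG2 at -1.94 and -1.39 and HBG1 at -1.70 and -1.23; the grey points slope upward in part because both axes share the KRAB_no_gRNA libraries.

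The comparisons of KRAB with dCas9 under the same gRNA ask what the repressor domain adds at HS2. With CR4, HBE1 fell 5.83-fold from 359 ± 38.2 CPM in dCas9_CR4, HBG2 fell 3.32-fold from 795 ± 105 CPM and HBG1 fell 2.85-fold from 730 ± 101 CPM (SD, n = 3), with edgeR adjusted p of 1.56e-08, 3.1e-05 and 0.000173. With CR10, HBE1 fell 4.48-fold from 381 ± 46.8 CPM in dCas9_CR10, HBG2 fell 2.23-fold from 784 ± 103 CPM and HBG1 fell 2.03-fold from 724 ± 98.3 CPM, with edgeR adjusted p of 1.66e-07, 0.0076 and 0.0293. These 3 were the only calls in each comparison. The cluster fell as a list with both gRNAs (camera adjusted p = 4.81e-40 with CR4 and 8.49e-42 with CR10, and adjusted p = 0.000723 and 0.000586 with an estimated correlation). Among the 6 cluster genes 5 were lower with CR4 and 4 with CR10 when adjusted over the list alone.

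DESeq2 called 5 genes with CR4, adding HBBP1 and PCSK1N, and 4 with CR10, adding PCSK1N. At an unadjusted p under 0.05 there were 147 genes with CR4 and 73 with CR10. The smallest p outside the clusters belonged with CR4 to PCSK1N, MS4A4A, CD8A, SERPINB8 and TM2D3, and with CR10 to PCSK1N, PGF, ZNF112, FANK1 and CA1, none of which passed in the edgeR fit of all 18 libraries. The lentiviral libraries with the block gave 8 and 7 calls, the same libraries without it 4 and 5, and the block on all 18 libraries 3 and 3. The 8 and 7 held HBBP1 and HBD (edgeR adjusted p = 9.7e-09 and 0.000164 with CR4, 8.42e-06 and 0.0212 with CR10). Outside the cluster they held ACSM3 (log2 fold change 1.36 ± 0.12 with CR4 and 1.10 ± 0.12 with CR10, SE), PCSK1N, and with CR4 TM2D3. On the lentiviral libraries without the block HBBP1 also passed (edgeR adjusted p = 0.000237 with CR4 and 0.029 with CR10). With CR10 so did PCSK1N (0.0296), which also passed on all 18 libraries with no count filter (0.0464) and with halved counts (0.0342). Without the block ACSM3 was at 1.38 with CR4, 0.71 without KRAB_CR4 library 3, and at 0.96 with CR10, 0.38 without KRAB_CR10 library 3, 0.63 without dCas9_CR10 library 1 and 1.88 without dCas9_CR10 library 3. The CR10 count fell to 1 gene, HBE1, when only KRAB_CR10 and dCas9_CR10 were fitted, when only lentiviral libraries numbered 1 and 2 were kept, and without dCas9_CR10 library 2, KRAB_CR10 library 2 or KRAB_CR10 library 3.

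Other lists passed camera with the preset correlation only. With CR4 these were the immediate early genes (adjusted p = 0.043, and adjusted p = 0.932 with an estimated correlation). With CR10 they were the interferon response and sterol synthesis (adjusted p = 0.0103 and 0.0101, and adjusted p = 0.397 and 0.499 with an estimated correlation). With the block the alpha-globin cluster and the unfolded protein and amino acid response also passed with CR10 (adjusted p = 0.00282 and 3.29e-05, and adjusted p = 0.366 and 0.389 with an estimated correlation).

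Averaged over both gRNAs, KRAB against dCas9 gave 4 calls. HBE1 fell 5.11-fold, from 370 ± 40 to 73.3 ± 15.1 CPM (SD, n = 6 and 6), HBG2 fell 2.72-fold and HBG1 fell 2.4-fold, with edgeR adjusted p of 1.59e-10, 2.14e-06 and 1.26e-05. The 1 gene that rose was PCSK1N (NM_013271), an X-linked gene that encodes proSAAS, an inhibitor of prohormone processing, from 0.387 ± 0.133 to 2.43 ± 0.754 CPM, 6.21-fold (log2 fold change 2.63 ± 0.35, SE; edgeR adjusted p = 0.00305). All 6 KRAB libraries with a gRNA lay above all 6 dCas9 libraries, but the gene was low, with 34 to 82 counts per KRAB library and 4 to 16 per dCas9 library, and the filter at a mean of 50 counts removed it. KRAB_no_gRNA read 0.961 ± 0.312 CPM and no_lentivirus 0.0617 ± 0.062 CPM (SD, n = 3). It stayed called in each of the 12 fits that left out 1 library, and lost the call with lentiviral libraries numbered 1 and 2 only (edgeR adjusted p = 0.237).

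The cluster fell as a list over both gRNAs (camera adjusted p = 1.39e-48, and adjusted p = 0.000282 with an estimated correlation). There were 186 genes at an unadjusted p under 0.05, and DESeq2 called 7, adding HBBP1, MS4A4A and TM2D3. The lentiviral libraries with the block gave 14 calls, the same libraries without it 5, and the block on all 18 libraries 5. Compared with the unblocked fit of all 18 libraries, the 14 added HBBP1, HBD and 8 genes outside the cluster, named after their values were seen. HBBP1 also passed with edgeR without the block: on the lentiviral libraries (adjusted p = 2.34e-05), with only the compared groups (0.000253) and with no count filter (0.00942). Higher with KRAB were ACSM3, AKAP11, APOBEC3B, MS4A3, MS4A4A and MYO16, and lower were CD8A and TM2D3, with ACSM3 at a blocked log2 fold change of 1.23 ± 0.09 (SE; edgeR adjusted p = 8.64e-09). Without the block ACSM3, AKAP11, APOBEC3B, CD8A, MS4A3 and MYO16 did not pass with edgeR or DESeq2. The interferon response and sterol synthesis lists passed camera (adjusted p = 0.025 for each, and adjusted p = 0.533 and 0.64 with an estimated correlation), and with the block so did the alpha-globin cluster and the immediate early genes (adjusted p = 0.0264 and 0.0173, and adjusted p = 0.45 for each with an estimated correlation).

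**Figure D4:**
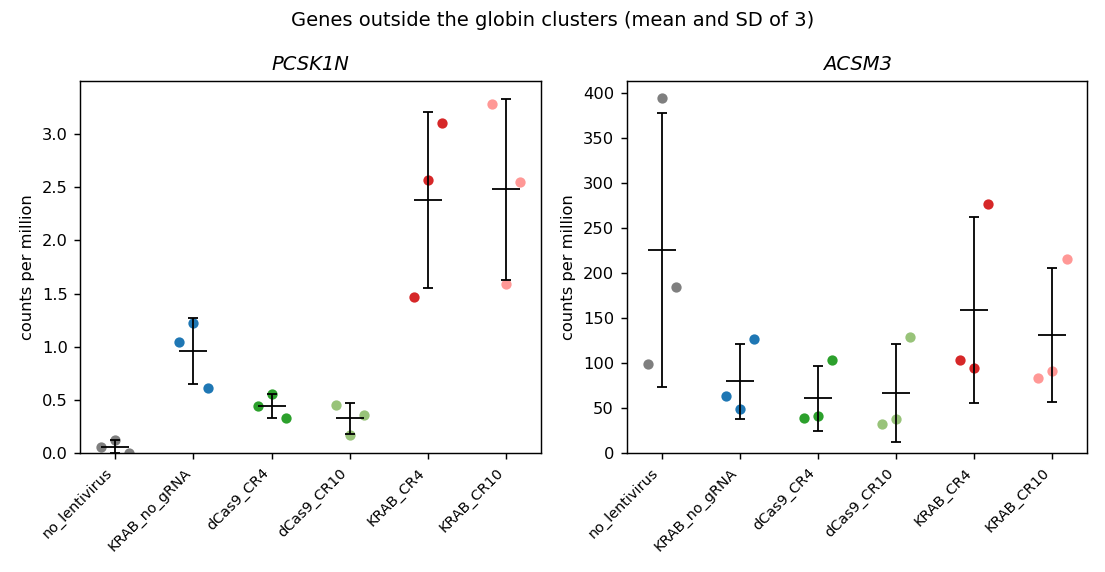
CPM of PCSK1N and ACSM3 in the 6 groups, on linear axes from 0; points are libraries in the order 1 to 3, the long bar is the mean and the whiskers the SD of 3 libraries. PCSK1N is at 2.38 and 2.48 in the KRAB groups with a gRNA against 0.446 and 0.328 in the dCas9 groups, and ACSM3 is highest in library 3 of each lentiviral group.

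The dCas9 groups against KRAB_no_gRNA ask whether a gRNA and dCas9 at HS2 act without a repressor domain. No gene passed in either comparison. HBE1 read 359 ± 38.2 CPM in dCas9_CR4 and 381 ± 46.8 CPM in dCas9_CR10 against 457 ± 17.8 CPM in KRAB_no_gRNA (SD, n = 3), which are log2 fold changes of -0.35 (95% interval -0.63 to -0.06) and -0.26 (-0.55 to 0.02), with an edgeR adjusted p of 1 in both. The dCas9_CR4 libraries did not overlap with KRAB_no_gRNA in HBE1, and with the block that difference passed over the list alone (adjusted p = 0.0108). HBG2 read 795 ± 105 and 784 ± 103 against 921 ± 31.4 CPM. As a list the cluster passed camera in both comparisons (adjusted p = 3.71e-05 and 0.0461) and in neither with an estimated correlation (adjusted p = 0.333 and 0.961). The comparison mixes the gRNA with the effector, since KRAB_no_gRNA differs from these groups in both.

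Genes of red cell membrane and maturation stood higher in both dCas9 groups than in KRAB_no_gRNA. The list passed in dCas9_CR4 (mean log2 fold change 0.22 over 21 genes, camera adjusted p = 2.29e-10, and adjusted p = 0.00391 with an estimated correlation). It also passed in dCas9_CR10 (0.21, camera adjusted p = 0.000167, and adjusted p = 0.0919 with an estimated correlation). No member passed over all genes, with or without the block. Haem synthesis genes also passed in dCas9_CR4 (0.12 over 18 genes; camera adjusted p = 1.93e-05, and adjusted p = 0.0196 with an estimated correlation). ALAS2, the first enzyme of erythroid haem synthesis, read 36.8 ± 4.05 against 24.5 ± 2.61 CPM, and passed over the list alone. The membrane list was higher in KRAB_CR4 and KRAB_CR10 as well (0.15 and 0.19; camera adjusted p = 0.000399 and 7.5e-05, and adjusted p = 0.0757 and 0.0443 with an estimated correlation; for KRAB_CR10 the latter was 0.0826 with the block), with CA1 passing over the list alone in both, so that all 4 groups with a gRNA lay on the same side of KRAB_no_gRNA, whose libraries all 4 comparisons share.

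In these 2 comparisons 66 genes (dCas9_CR4) and 175 genes (dCas9_CR10) had an unadjusted p under 0.05, and DESeq2 called 0 in each. The smallest p belonged to ALAS2, ABLIM1, KRIT1, EPB42 and TM2D3 in dCas9_CR4 and to PGF, EGR1, SH3BGRL2, FANK1 and PARD6B in dCas9_CR10. EGR1, an immediate early transcription factor, read 159 ± 67.3 against 74.8 ± 7.28 CPM, with an edgeR adjusted p of 1 over all genes and 0.0417 over the list alone, where FOS passed too. Hypoxia and glycolysis genes passed camera in dCas9_CR10 (adjusted p = 0.0281, and adjusted p = 0.25 with an estimated correlation). With the block the unfolded protein and amino acid response passed in both groups (adjusted p = 0.0154 and 0.000126, and adjusted p = 0.584 and 0.693 with an estimated correlation), and in dCas9_CR4 so did the alpha-globin cluster and sterol synthesis (adjusted p = 0.0154 and 0.00499, and adjusted p = 0.317 for each with an estimated correlation).

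**Figure D5:**
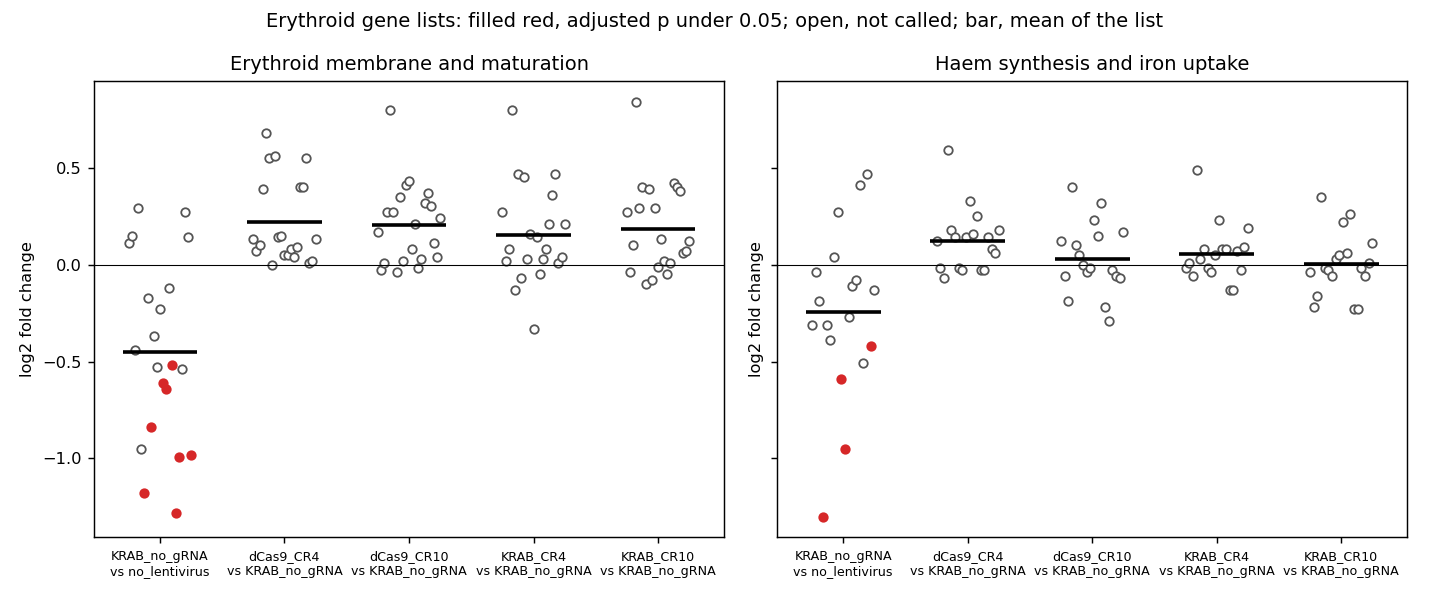
Log2 fold change of each tested gene of 2 lists, red cell membrane and maturation (21 genes) and haem synthesis and iron uptake (18 genes), in 5 comparisons; filled red points passed at an adjusted p under 0.05, open points did not, and the bar is the list's mean. In the first comparison 8 and 4 genes are red, all below 0, and the means of the membrane list in the other 4 comparisons lie between 0.15 and 0.22.

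Transduced cells without a gRNA were set against untransduced cells to show the joint change with the virus, the selection and dCas9-KRAB, which this comparison does not separate. Library numbers did not pair the untransduced libraries with the lentiviral ones, so any difference in culture or handling between them enters as well. Erythroid genes were lower in KRAB_no_gRNA. ALAS2 fell from 60.3 ± 0.615 to 24.5 ± 2.61 CPM (SD, n = 3 and 3; log2 fold change -1.30 ± 0.15, SE; edgeR adjusted p = 0.00143), the Rh blood group genes RHCE and RHD fell by 1.28 and 0.99 on the log2 scale, from 26.9 ± 3.2 to 11.1 ± 0.869 CPM and from 26.9 ± 3.21 to 13.5 ± 1.14 CPM (edgeR adjusted p = 0.00153 and 0.00495), and these 3 genes were called in each of the 6 fits that left out 1 library. None of the 3 passed when only these 2 groups were fitted. The antigen and membrane genes DMTN and XK fell by 1.18 and 0.98. Of 21 membrane and maturation genes 8 were lower and none higher (10 lower when adjusted over the list alone; camera adjusted p = 1.08e-05, and adjusted p = 0.0433 with an estimated correlation). Of 18 haem synthesis genes 4 were lower, among them ALAS2 and PPOX, and none higher (5 lower over the list alone, camera adjusted p = 0.00344, and adjusted p = 0.139 with an estimated correlation). These counts depend on single libraries. Without KRAB_no_gRNA library 1 only RHCE and RHD of the membrane list and ALAS2 of the haem list were called.

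HBE1 read 457 ± 17.8 against 604 ± 62.5 CPM, with an edgeR adjusted p of 0.0694 over all genes and 0.042 over the list alone, HBG1 and HBG2 did not pass, and HBQ1, a theta-globin gene, rose from 6.25 ± 0.393 to 11.1 ± 1.8 CPM (edgeR adjusted p = 0.0309). Among 20 erythroid transcription factors the master regulator GATA1 fell by 0.46 and BACH1 by 0.62 on the log2 scale and ZBTB7A rose by 0.89. GATA1 and ZBTB7A each lost their call in 5 of 15 alternatives, BACH1 in 6 and HBQ1 in 7. Of other cell type markers 1 of 10 myeloid and lymphoid genes was lower, PTPRC (CD45), from 223 ± 112 to 73.1 ± 9.21 CPM (edgeR adjusted p = 0.00891), and 2 of 11 megakaryocyte genes, TUBB1 and ITGB3. ITGB3 lost its call in 9 of 15 alternatives, TUBB1 in 2 and PTPRC in 1. The myeloid list's call (camera adjusted p = 0.023) was lost with an estimated correlation (adjusted p = 0.49).

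Interferon-induced genes were lower in 3 of 16 cases and higher in none: OAS3 fell from 14.2 ± 4.88 to 4.18 ± 0.934 CPM, IFIH1 from 5.28 ± 2.28 to 1.3 ± 0.27 CPM and IRF1 from 16.5 ± 4.49 to 9.56 ± 2.03 CPM, and the list passed with the preset correlation (camera adjusted p = 0.022) but not with an estimated one (adjusted p = 0.428). The AP-1 subunit JUND rose from 49.9 ± 14.1 to 139 ± 4.27 CPM and FOS, another subunit, fell from 12.1 ± 6.07 to 4.12 ± 1.3 CPM, the 2 immediate early genes of 13 that passed. The p53 targets held 1 higher gene, BAX, and 2 lower, CDKN1A and TP53INP1, among 17 (edgeR adjusted p = 0.0499, 0.0285 and 0.0404). BAX lost its call in 9 of 15 alternatives, and CDKN1A and TP53INP1 each lost theirs in 6 of 15. HP1-gamma, encoded by CBX3, rose by 0.70 on the log2 scale, the only 1 of 16 KRAB co-repressor genes to pass.

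The largest rises among genes without overlap between the groups were those of PCSK1N, CCDC78, EME2, NPW, FJX1, NPB, SNHG9, AMH, ARHGAP27P1 and VGF. PCSK1N rose from 0 to 4 counts per untransduced library to 16 to 32 counts, a log2 fold change of 3.85 ± 0.63 (SE) that lay between 3.31 (without no_lentivirus library 3) and 4.73 (without library 2) when 1 library was left out. NPW, a neuropeptide precursor, rose from 0.441 ± 0.129 to 2.79 ± 0.82 CPM, and VGF, another secreted peptide precursor, from 1.67 ± 0.842 to 6.01 ± 0.725 CPM (edgeR adjusted p = 0.00197 and 0.0137, and 0.00857 for PCSK1N). The largest falls were those of G0S2, UNC5B, S100P, ASS1, ADGRA2, TCP11L2, RASGRP3, SH3BGR, HECW2 and PHGDH. These rested on unequal untransduced libraries: G0S2 read 17.1 ± 19.4, UNC5B 49.8 ± 56.4, ASS1, an enzyme of arginine synthesis, 40.3 ± 43.9 and PHGDH, the first enzyme of serine synthesis, 231 ± 211 CPM in no_lentivirus. The list of the unfolded protein and amino acid response, to which PHGDH and the chaperone HSPA5 belong as the 2 lower of 16 genes, passed with the preset correlation (camera adjusted p = 0.00279) and not with an estimated one (adjusted p = 0.49).

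In all 976 genes passed with edgeR, 423 higher and 553 lower in KRAB_no_gRNA, and DESeq2 called 2008. This count rests on single libraries. It was 27 without KRAB_no_gRNA library 1, 215 without library 2 and 238 without library 3, and 2447, 41 and 207 without no_lentivirus libraries 1, 2 and 3, and it was 0 when only these 2 groups were fitted. All 976 kept their sign in the 6 fits that left out 1 library, and 20 genes, 9 higher and 11 lower, were called in each of them, among them ALAS2, RHCE, RHD, PTPRC, OAS3, JUND, NPW and PCSK1N. The 2 groups did not overlap in 26.4% of the tested genes, against 2.61% to 8.86% in the other comparisons of 3 with 3 libraries. Exchangeable libraries would give 10% for a single gene, but genes are not independent, so 10% is not a baseline for the share over all genes. ZNF10, the source of the KRAB domain, read 6.48 ± 1.09 CPM in KRAB_no_gRNA and 7.87 ± 0.174 CPM in no_lentivirus (edgeR adjusted p = 0.407). Of the 27 neighbours of the beta-globin cluster 5 were lower, among them ILK and TRIM6 (list camera adjusted p = 0.0735).

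The 2 gRNAs were compared directly with KRAB and through the difference of their KRAB effects. The beta-globin genes were lower with CR4 than with CR10. HBE1 read 61.6 ± 6.2 against 85.0 ± 11 CPM, HBG2 240 ± 22.5 against 351 ± 50.4 CPM and HBG1 257 ± 21.3 against 357 ± 43.6 CPM (SD, n = 3 and 3), log2 fold changes of -0.46 ± 0.13 (SE), -0.55 ± 0.16 and -0.48 ± 0.16, with no overlap between the groups. Adjusted over the list alone these 3 genes passed (edgeR adjusted p = 0.00785, 0.00785 and 0.0153), whereas over all genes none did. The cluster passed camera (adjusted p = 2.39e-09), but not with an estimated correlation (adjusted p = 0.199).

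Taking each gRNA's dCas9 group into account, the difference of the KRAB effects was -0.38 ± 0.19 (SE) for HBE1, -0.57 ± 0.22 for HBG2 and -0.49 ± 0.22 for HBG1, and no gene passed over all genes or over the list alone. With the block HBG2, HBG1, HBBP1 and HBE1 passed over the list alone (edgeR adjusted p = 0.00218, 0.00286, 0.00286 and 0.0191). The cluster passed camera (adjusted p = 9.91e-06) but not with an estimated correlation (adjusted p = 0.667). In the direct comparison 132 genes and in the difference 51 genes had an unadjusted p under 0.05, DESeq2 called 0 in both, and the block called 0 in both over all genes. The smallest p outside the clusters belonged to SERPINB8, CHST8, CD8A, GARIN1A and AURKAP1 in the first and SNTN, UXT-AS1, MYLK, SERPINB8 and RTKN2 in the second, none of which passed. Replication-dependent histones passed camera in both (adjusted p = 0.000618 and 0.0116, and adjusted p = 0.395 and 0.8 with an estimated correlation) and cell cycle genes in the first (adjusted p = 0.0281, and adjusted p = 0.826 with an estimated correlation). With the block the unfolded protein and amino acid response passed in both (adjusted p = 0.0132 and 2.51e-06, and adjusted p = 0.669 and 0.728 with an estimated correlation).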

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

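The differences between the gRNAs were tested as planned, and the fit with the replicate block on the lentiviral libraries alone was chosen only after the result was seen. The fall of the beta-globin genes differed between the 2 gRNAs by a test of the difference itself, adjusted over the cluster's list alone. Against the shared KRAB_no_gRNA control, the difference between KRAB_CR4 and KRAB_CR10 was -0.46 for HBE1, -0.48 for HBG1 and -0.55 for HBG2 on the log2 scale (edgeR adjusted p = 0.00785, 0.0153 and 0.00785), with every KRAB_CR4 library below every KRAB_CR10 library. Taken against each gRNA's own dCas9 group no gene passed without the block, and with it the difference was -0.80 for HBBP1, -0.39 for HBE1, -0.49 for HBG1 and -0.57 for HBG2 (edgeR adjusted p = 0.00286, 0.0191, 0.00286 and 0.00218). None of these differences passed over all genes. No technical or biological explanation was tested.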

How the results depend on the processing

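Chosen only after the data were seen were the tests on lentiviral libraries alone, with or without the block, those on halved counts, without libraries numbered 3 or without ribosomal RNA, and the shared calls against the dCas9 groups without globin genes. HBE1 kept its direction and its call in every alternative for the 5 comparisons of KRAB with a gRNA. HBG1 and HBG2 lost the call under some alternatives for KRAB_CR10: against dCas9_CR10 the count was 1 when only the groups compared were fitted and 1 with lentiviral libraries numbered 1 and 2 only, and against KRAB_no_gRNA it was 1 with the latter. Leaving out 1 library each gave 3 to 3 calls for KRAB_CR4 and for KRAB_CR10 against KRAB_no_gRNA and for KRAB_CR4 against dCas9_CR4, 1 to 3 for KRAB_CR10 against dCas9_CR10 (1 without dCas9_CR10 library 2, KRAB_CR10 library 2 or KRAB_CR10 library 3), 4 to 4 over both gRNAs, and 0 to 0 in the 4 comparisons that called 0. With DESeq2 the counts were 6 for KRAB_CR4 against KRAB_no_gRNA, 5 for KRAB_CR4 against dCas9_CR4 and 7 over both gRNAs. With lentiviral libraries only the count for KRAB_CR10 against dCas9_CR10 was 5. With the replicate block on the lentiviral libraries the counts were 6 and 7 against KRAB_no_gRNA, 8 and 7 against the dCas9 groups and 14 over both gRNAs; the block on all 18 libraries gave 3, 3, 3, 3 and 5, and neither block called a gene in the comparisons that called 0. The cause of these shifts was not tested.

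KRAB_no_gRNA against no_lentivirus, 976 calls, depended most on the processing: 29 at an adjusted p under 0.01, 2008 with DESeq2, 0 with only the groups compared, 2621 with the replicate block on all 18 libraries, which the untransduced libraries do not pair with, 1617 with lentiviral libraries numbered 1 and 2 only, and 27 to 2447 without 1 library, the lowest without KRAB_no_gRNA library 1 and the highest without no_lentivirus library 1; the cause was not tested. With no filter, a stricter filter, other size factors, summed paralogs, halved counts or no ribosomal RNA it stayed between 884 and 1127. Of the gene list tests 31 passed over the 10 comparisons, 9 with an estimated correlation, 33 with the replicate block and 26 to 37 without 1 library. The shared calls of the gRNAs, 3, were by construction 0 without the globin cluster genes, which held every call by either control. They were 6 with the block on lentiviral libraries, 7 with that block against the dCas9 groups, and 3 to 3 without 1 library. PCSK1N over both gRNAs lost its call with lentiviral libraries numbered 1 and 2 only. Of the named genes, HBG1 and HBG2 turned direction in KRAB_no_gRNA against no_lentivirus, where they were not called: without no_lentivirus library 2 the log2 fold changes were -0.07 and -0.03, and without library 1 they were 0.25 and 0.25. In the fit of all 18 libraries, changes of 1.5-fold were mostly out of reach at this depth and spread.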

Other observations

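Chosen only after the result was seen were the test of the libraries numbered 3 against untransduced cultures, the comparison of KRAB_no_gRNA with the mean of the other 5 groups, and the test of how far KRAB without a gRNA moves the genes outside the globin cluster. The 5 lentiviral libraries numbered 3 differed from those numbered 1 and 2 in 7857 of 14599 genes (edgeR adjusted p under 0.05, in a fit with group and all 3 numbers), 4075 higher and 3782 lower. In the same fit libraries numbered 1 differed from the mean of numbers 2 and 3 in 4685 genes. Those numbered 2 differed from the mean of numbers 1 and 3 in 2800. Number 3 enters both contrasts, so these counts can restate its difference, and numbers 1 and 2 were not set against each other. In libraries numbered 3, genes of the unfolded protein and amino acid response were higher in 12 of 16 cases and lower in 1 (camera adjusted p = 3.41e-06, and adjusted p = 0.338 with an estimated correlation). Of these, CHAC1, which degrades glutathione, rose by 2.95 on the log2 scale, the serine synthesis enzyme PHGDH by 1.19, the pseudokinase TRIB3 by 0.93 and asparagine synthetase ASNS by 0.72. Outside that list, and chosen after their values were seen, INHBE rose by 2.52, the mTORC1 inhibitor DDIT4 by 2.34, GDF15 by 1.89, ERBB3 by 1.87 and ACSM3 by 1.46.

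Erythroid transcription factors were lower in 13 of 20 cases and higher in none (camera adjusted p = 0.000388, and adjusted p = 0.194 with an estimated correlation), and the embryonic alpha-like globin gene HBZ fell by 0.54. All 8 tested myeloid and lymphoid markers were higher (0.000806, and adjusted p = 0.194 with an estimated correlation). KRAB co-repressors were lower in 10 of 16 cases (0.00184; 0.194), cell cycle genes in 13 of 23 (0.00649; 0.387), and sterol synthesis genes were higher in 9 of 16 (0.0106; 0.351), the second value of each pair being the camera adjusted p with an estimated correlation.

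In 100 draws of 1 library from each lentiviral group, out of 243 possible, the draw was set against the rest in a fit with group alone, which leaves other differences between numbers in the residual and lowers the counts. The real draw called 7381 genes and the highest other, with 4 of the 5 libraries numbered 3, called 1946, so 1 of 100 reached the real count; number 3 was singled out after it stood apart, so this asks only whether the libraries that stand apart share a number, not why. With every library thinned to the lowest total 95.4% of the calls remained, and with the trend on GC content and transcript length removed 91.5% remained, so neither accounts for the difference. Across genes it correlated at 0.46 with the first principal component of the 3 untransduced libraries, whose arbitrary sign was set to give a positive value. That component mainly set no_lentivirus library 2 (loading 0.76) against library 1 (-0.64). No simulated value was set beside the correlation, so it cannot tell whether a culture state that untransduced cells also show contributes. Culture density and handling day were not recorded and stay untested.

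Red cell membrane and maturation genes were lower in KRAB_no_gRNA than in the mean of the other 5 groups (mean log2 difference -0.24), a comparison set up after the list was seen lower in each of the 5 comparisons that share these libraries, so its p is not separate evidence. The list still passed camera in it with libraries thinned to the lowest total (4.17e-09) and with the GC content and length trend removed (5.33e-12), so these do not account for it. Without library 1, 2 or 3 the mean log2 difference was -0.24, -0.28 and -0.25, so no 1 of the 3 libraries carries it alone; the highest camera adjusted p was 0.000288, without library 3, where it was 0.0913 with an estimated correlation. The other 5 groups include no_lentivirus, which has no gRNA either, so the pooled value also holds the change from untransduced cells. Whether the missing gRNA or a difference between transductions lies behind the difference from the groups with a gRNA stays untested.

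With the replicate block 9 genes outside the beta-globin cluster differed between KRAB and dCas9. All 9 passed after thinning to the lowest total and 9 after removal of the GC content and length trend, so neither accounts for them. KRAB_no_gRNA reached a median share of 0.49 of the difference (quartiles 0.43 and 0.53), with single genes from 0.06 (AKAP11) to 0.88 (MYO16), so the genes as a group cannot tell whether the gRNA is needed; they were chosen because the KRAB libraries with a gRNA differed from dCas9, which biases these shares, and the unadjusted p under 0.05 of 7 of the 9 genes for KRAB with against without a gRNA, by an unknown amount. ACSM3 alone of the 9 also passed among all genes against KRAB_no_gRNA, with both gRNAs. It did so only with the block on the lentiviral libraries (edgeR adjusted p = 0.00044 and 0.0271). In the unblocked fit of all 18 libraries it passed with neither gRNA (edgeR adjusted p = 0.999 for each). ACSM3 was chosen in the same way as the others, so these values do not settle whether it needs the gRNA. Binding of dCas9 outside HS2 was not measured and stays untested.

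Other splits of the same libraries were refitted. For comparisons of 3 with 3 libraries the 10 splits are too few to exclude chance. The real split called 3 genes and the highest other 0 for KRAB_CR4 and KRAB_CR10 against KRAB_no_gRNA and against their dCas9 groups, 976 and 0 for KRAB_no_gRNA against no_lentivirus, 0 and 0 for dCas9_CR4 against KRAB_no_gRNA and for KRAB_CR4 against KRAB_CR10, and 0 and 8 for dCas9_CR10 against KRAB_no_gRNA. Of the splits 1 reached the real count in each of the 5 comparisons with calls. In each of the 3 without calls 10 did, which had to be so, since no count lies below 0. Over both gRNAs 2 of 100 splits called as many genes as the real 4; the highest other, 867, put all 4 libraries numbered 3 on the same side. Swapping effector labels within same-numbered pairs under the block, 1 of 32 swaps reached the real 14 and the highest other called 3. For the difference of the KRAB effects 100 of 100 splits reached the real 0, with 867 the highest. Every split reaches a count of 0, so this test is uninformative.

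The count of gene lists that passed camera with the preset correlation was often reached by other splits. Of 10 splits, again too few, it was reached by 9 for KRAB_CR4 and 4 for KRAB_CR10 against KRAB_no_gRNA (real 3 and 4, highest other 7 and 7), by 6 and 5 against the dCas9 groups (real 2 and 3, highest other 8 and 8), by 5 for dCas9_CR4 and 6 for dCas9_CR10 against KRAB_no_gRNA (real 3 and 3, highest other 9 and 7), by 5 for KRAB_no_gRNA against no_lentivirus (real 5, highest other 8) and by 6 for KRAB_CR4 against KRAB_CR10 (real 3, highest other 8). Over both gRNAs 49 of 100 splits reached the real 3 and for the difference of the KRAB effects 73 of 100 reached the real 2, with 8 the highest other in both.

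Most of these splits ignore the pairing by library number. Among the 4 splits, the real one included, that put the libraries of every same-numbered pair on opposite sides, the highest other count was 1 for KRAB_CR4 against dCas9_CR4 (real 2), 2 for KRAB_CR10 against dCas9_CR10 (real 3), 1 for each dCas9 group against KRAB_no_gRNA (real 3 and 3) and 3 for KRAB_CR10 against KRAB_no_gRNA (real 4). It was 4 for KRAB_CR4 against KRAB_no_gRNA (real 3) and 5 for KRAB_CR4 against KRAB_CR10 (real 3), and 4 splits are too few to exclude chance.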
